A study of Mus musculus with 4 samples.

How the data were processed

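Chromatin immunoprecipitation followed by sequencing (ChIP-seq) had been carried out on mouse embryonic fibroblasts, in 4 libraries, 1 per group. One library was made with rabbit IgG as the background control, and 3 with an antibody against TFE3, from cells in full medium (control), starved cells and tunicamycin-treated cells. Per the labels' protocols, the culture medium held 10% serum, starvation was 2 hours in a balanced salt solution, tunicamycin was given at 0.1 µg/ml over 16 hours, and cells were fixed in 1% formaldehyde before sonication.

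The 3 TFE3 libraries each had a peak list. The IgG library entered only as the background of those lists. Bowtie, MACS2 and the mouse build mm9 are named in the submitters' processing notes, with no version or role. Each list has the 10 fields of a MACS2 narrowPeak file and peak names that pair a TFE3 library with a negative control, so peaks had been called per library and not on pooled samples. The authors deposited for each peak a score, a fold enrichment at the summit as a linear ratio over local background, the −log10 of a p-value and of a q-value, and the summit's distance from the peak start. The deposited score equalled the whole part of 10 times the −log10 q in 100% of peaks of each list. The lowest −log10 q was 1.57 in the control list, 1.65 in the starvation list and 1.45 in the tunicamycin list, and the lowest −log10 p was 5.85, 5.27 and 4.70 in the same order. The scores and folds are the authors' values. They were used to describe and rank peaks within a list, to apply 1 score threshold to all lists as an alternative, and, for the fold, to recover tag numbers. Folds of different lists stand side by side as descriptions, each against the background of its own list.

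Depth was recovered from the deposited fold and −log10 p, because no read totals were among the files used here. Under MACS2's formulas, with a pseudocount of 1, the fold is the scaled number of tags over the summit plus 1, divided by the local background plus 1, and p is a Poisson tail of the same numbers. One scale per list gave a single whole number of tags, with p met within 0.004 on the −log10 scale, for 422 of 422 control peaks (100%), 1703 of 1712 starvation peaks (99.5%) and 2767 of 2776 tunicamycin peaks (99.7%). After p was shuffled among peaks of the same list, a whole number was found for 3.55%, 3.27% and 3.53%. The scale of 1 TFE3 tag was 0.650, 0.618 and 0.466, so the TFE3 libraries were 1.54, 1.62 and 2.14 times as deep as the IgG library. The genome-wide background was 1.79, 2.32 and 2.55 tags per fragment length. Divided by the shortest peak of each list (149, 193 and 212 bp), which MACS2 sets to its fragment length, it came to 12.0 IgG tags per kb in each list. These formulas are not recorded in the labels. On simulated lists of the same sizes the recovery resolved 100%, 98.6% and 98.6% of peaks and gave the simulated tag number for 100% of those resolved. The simulated lists were made with the same formulas, so they check the inversion and not whether the formulas hold. Their tag numbers also stopped short of the highest recovered ones.

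Peaks of different lists were called shared at an overlap of at least 1 bp. Shares carry 95% exact Clopper-Pearson intervals, which cover counting error over peaks only, and tag numbers carry 95% exact Poisson intervals with the same limit. For a count of 0 the limit given is 3 counts of the total. The overlap that position alone would give was measured with 1000 circular shifts of 1 list within each chromosome, between 0 and the highest peak end seen in any list. Shifted peaks can fall anywhere in that span, so the shifts do not account for sites that any library would favour. On simulated lists of 2000 and 1500 peaks with 700 shared, 700 were found. Scores of shared and unshared peaks were compared within a list, beside 10000 random relabellings of its peaks. Repeats of this comparison under other settings used 2000 relabellings, as did the range that set whether a difference stayed. Regions of the union were made by merging peaks that overlapped by at least 1 bp. With 1 library per group there is no replicate, no test between conditions was made, and every difference compares libraries. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

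The design, the alternatives and the rule for named peaks were fixed before the data were examined. The rule named the 10 peaks of highest score in each list and the 10 regions with the best mean rank among regions called in all 3 lists. Alternatives covered the score threshold, the overlap that counts as shared, lists of equal length, peak width and the merging of peaks within 500 bp. Promoter share, gene lists and E-box content were also planned. They needed an mm9 sequence and annotation, which was not used here, and a gene table of another assembly was not matched to mm9 positions, so peaks are named by mm9 position and not by gene. Coordinates are 1-based.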

Results

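TFE3, a basic helix-loop-helix leucine zipper transcription factor of the MITF/TFE family, was profiled by ChIP-seq in mouse embryonic fibroblasts under 3 conditions: full medium (control), 2 hours of starvation in a balanced salt solution, and 16 hours with 0.1 µg/ml tunicamycin. Tunicamycin blocks N-linked glycosylation and so causes endoplasmic reticulum stress. Each condition had 1 TFE3 library, and 1 IgG library from the same cell type served as background. The recovered depth of the TFE3 libraries relative to IgG was 1.54 for control, 1.62 for starvation and 2.14 for tunicamycin. The series asks how this transcription factor family takes part in the response to nutrient and endoplasmic reticulum stress, and the lists compare where TFE3 was found on chromatin in unstressed and stressed cells. All positions are in mm9, and the data give no replicate of any condition.

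The control list held 422 TFE3 peaks, the starvation list 1712 and the tunicamycin list 2776. The starvation list was thus 4.06 times as long as the control list at 1.05 times its depth, and the tunicamycin list was 6.58 times as long at 1.39 times its depth. The peaks covered 103 kb in control, 493 kb in starvation and 839 kb in tunicamycin. Median peak width was 216 bp (interquartile range 176 to 288), 266 bp (223 to 323) and 286 bp (242 to 342) in the same order, and the shortest peak, which follows the fragment length of the library, was 149, 193 and 212 bp. The authors' median fold enrichment at the summit was 6.15 in the control list, 6.43 in the starvation list and 6.32 in the tunicamycin list, while the highest was 15.3, 25.8 and 27.2. A peak summit rested on a median of 30 TFE3 tags in control (range 19 to 118), 37 in starvation (20 to 223) and 53 in tunicamycin (26 to 306).

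Merging the 3 lists gave 3415 regions. Of these, 169 were called in all 3 lists (4.95%, 95% interval 4.25 to 5.73), and 1122 in starvation and tunicamycin but not in control (32.9%, 31.3 to 34.5). A further 1484 regions were called in tunicamycin only (43.5%, 41.8 to 45.1), 388 in starvation only and 220 in control only. The tunicamycin library was 1.33 times as deep as the starvation library, with fragments 1.10 times as long, and it was not thinned to that library. Control and starvation without tunicamycin shared 32 regions. Control and tunicamycin without starvation shared 0 of the 3415, which allows a share of up to 0.0878% (3 counts of the total). The order of these classes depends on how the lists are cut. At a common score of at least 68, the control median, it was nearly kept. There 1133 regions were in tunicamycin only, 846 in starvation and tunicamycin, 258 in starvation only, 114 in all 3 lists and 92 in control only. The order was another in lists of equal length, which hold the whole control list but only the strongest peaks of the stress lists. With the top 422 peaks of each list, 254 regions were in control only and 149 in all 3 lists. A further 139 were in tunicamycin only, 133 in starvation only and 128 in starvation and tunicamycin.

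**Figure D1:**
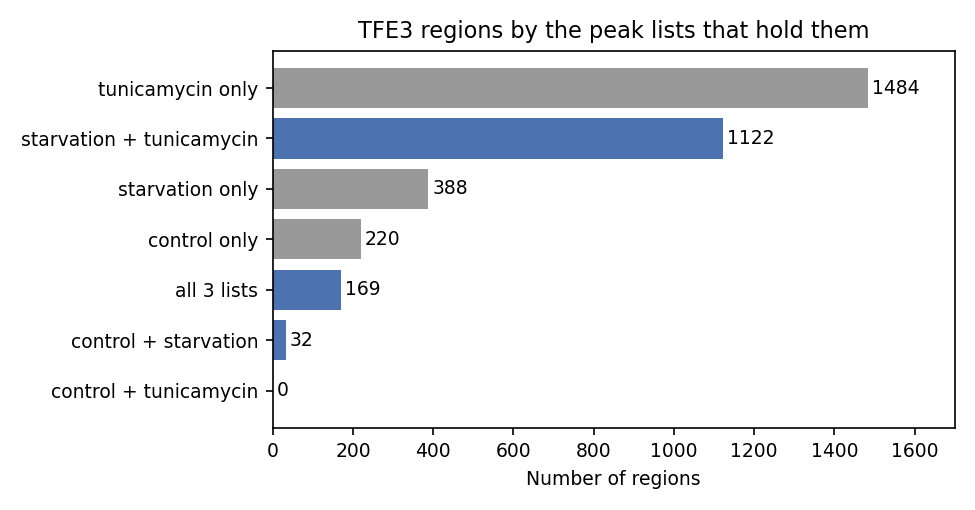
Horizontal bars give the number of merged TFE3 regions (x axis) for each combination of peak lists (y axis), with grey for regions in 1 list and blue for regions in several. The longest bars are the 1484 tunicamycin-only regions and the 1122 regions of starvation and tunicamycin, and 0 regions were in control and tunicamycin without starvation.

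The first comparison sets starved cells against cells in full medium. Of the 422 control peaks, 202 lay under a starvation peak (47.9%, 95% interval 43.0 to 52.8), and of the 1712 starvation peaks, 201 lay under a control peak (11.7%, 10.3 to 13.4). The other 1511 starvation peaks had no counterpart in the control list. Circular shifts of the control peaks gave a mean of 0.186 overlaps and a highest of 3, so the overlap was far above that of position alone. Starvation peaks found in control were mostly the strongest: 161 of the 428 peaks in the highest 25% by score were called in control (37.6%, 33.0 to 42.4), against 18 of 428 in the lowest (4.21%, 2.51 to 6.57). Where both lists held a peak, the summits lay a median of 18 bp apart, and 168 of 202 (83.2%, 77.3 to 88.1) were within 50 bp. The share of control peaks also called in starvation was 33.6% when each peak had to cover 50% of the other. The length of the control list limits the share of starvation peaks found there. With the top 422 peaks of each list that share was 38.2% (33.5 to 43.0). As the control list holds 422 peaks, this cut shortened only the starvation list, to its strongest peaks. The value thus nearly repeats that of the highest 25% by score and does not separate list length from score.

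The region of highest score in the starvation list was on chromosome 15 at 80085560 to 80086068, with a fold enrichment of 23.7 and 153 tags at the summit (95% interval 130 to 179). It was followed by chromosome 2 at 164658971 to 164659521, at 25.8-fold with 137 tags (115 to 162), and chromosome 19 at 4201421 to 4202064, at 17.8-fold with 171 tags (146 to 199). All 10 of the highest-scored starvation peaks lay in regions called in all 3 lists. The strongest starvation peak without a control or tunicamycin peak, singled out after its value was seen, was on chromosome 19 at 5846670 to 5847133, with a fold of 10.5 and 61 tags (46.7 to 78.4). The strongest starvation peak shared with tunicamycin but not control was on chromosome 3 at 87981503 to 87981905, with a fold of 17.2 and 91 tags (73.3 to 112), also chosen after its value was seen.

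The second comparison sets tunicamycin-treated cells against control cells. Of the 422 control peaks, 170 lay under a tunicamycin peak (40.3%, 35.6 to 45.1). Of the 2776 tunicamycin peaks, 169 lay under a control peak (6.09%, 5.23 to 7.04), which left 2607 without a counterpart. Circular shifts gave a mean of 0.296 overlaps for the control peaks and a highest of 3. Of the 694 tunicamycin peaks in the highest 25% by score, 158 were called in control (22.8%, 19.7 to 26.1), against 3 of 694 in the lowest (0.432%, 0.0892 to 1.26). Summits of shared peaks lay a median of 15 bp apart, and 152 of 170 were within 50 bp (89.4%, 83.8 to 93.6). With the 50% reciprocal rule the share of control peaks found in tunicamycin was 16.8%, and the share of tunicamycin peaks found in control was 2.56%. In the regions of all 3 lists the median width was 207.5 bp for control peaks and 457 bp for tunicamycin peaks. A peak of the first width cannot cover 50% of a peak of the second, so width alone lowers these shares. At an overlap of 1 bp, the share of tunicamycin peaks found in control was 3.89% among those at the genome-wide background. It was 36.7% (32.1 to 41.5) with the top 422 peaks of each list. That cut shortened only the tunicamycin list, to its strongest peaks, so it does not separate list length from score.

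In the tunicamycin list the highest score belonged to chromosome 19 at 4201414 to 4202047, with a fold enrichment of 22.2 and 298 tags at the summit (265 to 334). Chromosome 11 at 51814103 to 51814647 followed at 26.1-fold with 241 tags (212 to 273), and chromosome 7 at 52721905 to 52722522 at 27.2-fold with 231 tags (202 to 263). As in starvation, all 10 of the highest-scored peaks were in regions called in all 3 lists. Among the 1484 tunicamycin-only regions the strongest peak, picked after its value was seen, was on chromosome 14 at 60584484 to 60584849, with a fold of 13.4 and 100 tags (81.4 to 122). The tunicamycin-only peaks had a median fold of 5.66 (interquartile range 5.03 to 6.58), and the tunicamycin peaks of the 169 regions in all lists had a median of 14.1 (11.7 to 18.0).

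The third comparison sets the 2 stresses side by side. Of the 1712 starvation peaks, 1292 were also called in tunicamycin (75.5%, 73.4 to 77.5), and the same number of the 2776 tunicamycin peaks were called in starvation (46.5%, 44.7 to 48.4). Both shares count 1292 peaks, so they are unequal only because the tunicamycin list, from the deeper library, is longer. With the top 422 peaks of each list, where the lengths are equal by choice, the share was 65.6% (60.9 to 70.2) either way. Circular shifts of the starvation peaks reached 6 overlaps at most, with a mean of 1.23. The overlap climbed with score in each list. In the starvation list it was 48.8% (44.0 to 53.7) in the lowest 25% by score and 97.7% (95.7 to 98.9) in the highest, where 418 of 428 peaks were shared. In the tunicamycin list it was 22.0% (19.0 to 25.3) in the lowest and 89.3% (86.8 to 91.5) in the highest. Summits of the 1292 shared peaks lay a median of 14 bp apart, and 1166 (90.2%, 88.5 to 91.8) were within 50 bp. Both lists were called against the same IgG library, so part of the overlap above shifted positions may come from that shared background. Among the 757 starvation peaks whose local background equalled the genome-wide value, so that no local IgG signal entered the call, 79.0% (75.9 to 81.8) were shared, and among the 946 with a higher local background 72.4% (69.4 to 75.2) were. The tunicamycin list went the other way: 42.4% (39.7 to 45.1) of its 1337 peaks at the genome-wide value were shared with starvation, against 50.5% (47.9 to 53.1) of the 1430 above it.

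**Figure D2:**
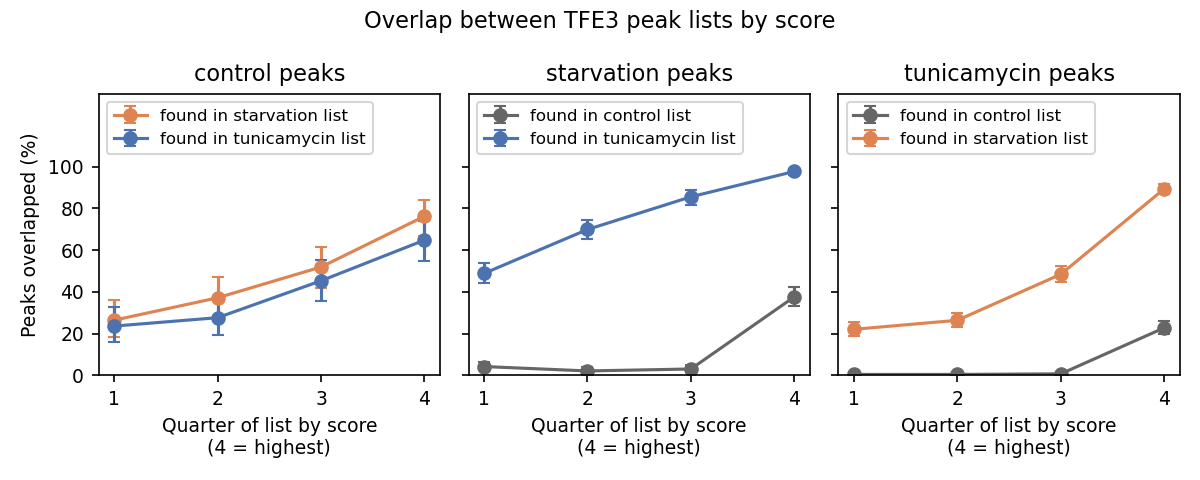
Each panel takes the peaks of 1 list in 4 equal parts by the authors' score (x axis) and gives the percentage overlapped by another list (y axis), with 95% exact binomial intervals as bars. The share of starvation peaks found in tunicamycin runs from 48.8% to 97.7%, and the share of tunicamycin peaks found in starvation from 22.0% to 89.3%.

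Shared peaks had higher scores than unshared ones within each list. The median score was 93 for the 202 control peaks found in either stress list and 55.5 for the other 220, a difference of 37.5 against −19.5 to 20.5 over 10000 relabellings. In the starvation list it was 110 for peaks shared with tunicamycin and 60 for the rest, a difference of 50 (relabellings −20 to 15.5). In the tunicamycin list it was 168 for peaks shared with starvation and 78 for the rest, a difference of 90 (−14 to 15). Shared tunicamycin peaks were also wider, at a median of 340 bp against 251 bp. Within the narrower 50% of each list, set beside fewer relabellings, the score difference was smaller, at 16.5 in control (relabellings −14 to 12) and 17 in starvation (−8 to 12). In the tunicamycin list it was 8, which did not exceed its relabellings (−8 to 8).

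The regions called in all 3 lists held the strongest TFE3 sites of the stress lists. In these regions the median fold enrichment of the peaks was 6.87 in the control list (interquartile range 5.61 to 8.48), 12.2 in the starvation list (9.83 to 15.7) and 14.1 in the tunicamycin list (11.7 to 18.0), each against its own background. The best mean rank over the lists belonged to the region on chromosome 19, which ranked first in control (4201552 to 4201923, fold 12.2, 92 tags with an interval of 74.2 to 113), 3 in starvation and 1 in tunicamycin. Next came chromosome 6 at 54816795 to 54817095 in the control list, with folds of 11.9, 17.4 and 19.7 in control, starvation and tunicamycin. Chromosome 11 at 51814176 to 51814601 had folds of 12.5, 22.1 and 26.1, and chromosome 7 at 52722073 to 52722385 had 13.4, 23.9 and 27.2. The remaining 6 were on chromosomes 6 (from 108135447), 2 (from 164659060 and from 101726235), 17 (from 46783190), 3 (from 89006631) and 8 (from 97125581). Over these 10 regions the fold ran from 11.9 to 15.3 in control, from 17.4 to 25.8 in starvation and from 19.7 to 27.2 in tunicamycin. Summits at the chromosome 19 region were at 4201735, 4201743 and 4201745 in control, starvation and tunicamycin.

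**Figure D3:**
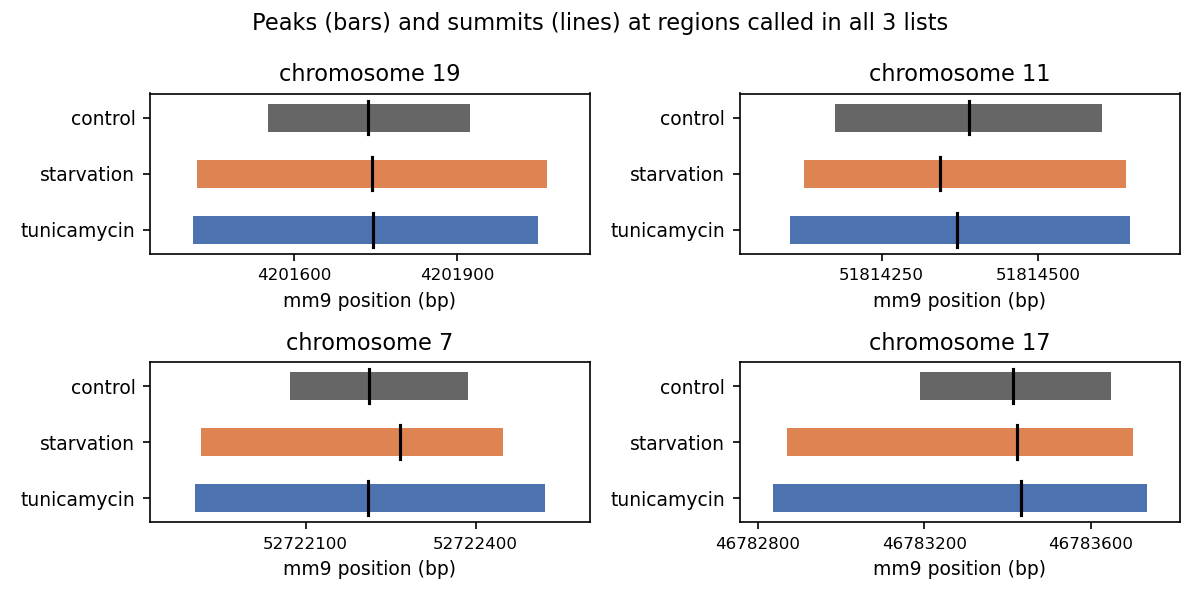
Bars show the extent of the peak in each list (y axis) along mm9 in bp (x axis) at 4 of the 10 regions with the best mean rank, on chromosomes 19, 11, 7 and 17, and black lines mark the summits. The control peak is the narrowest in each panel, and at chromosome 19 the summits lie between 4201735 and 4201745.

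In the control list, 8 of the 10 highest-scored peaks lay in regions called in all 3 lists, and 2 were in control only. These were chromosome 7 at 91477693 to 91478319, with a fold of 12.0 and 72 tags (56.3 to 90.7), and chromosome 13 at 25716529 to 25717134, with a fold of 13.6 and 61 tags (46.7 to 78.4). The 220 control-only peaks had a median fold of 5.88 (interquartile range 5.01 to 6.72) and rested on a median of 28 tags. Of the 105 control peaks in the highest 25% by score, 80 were found in starvation (76.2%, 66.9 to 84.0) and 68 in tunicamycin (64.8%, 54.8 to 73.8).

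Peaks lay on all 19 autosomes and on X in each list. Chromosome X carried 4 of 422 control peaks, 14 of 1712 starvation peaks and 13 of 2776 tunicamycin peaks, or 0.948% (0.259 to 2.41), 0.818% (0.448 to 1.37) and 0.468% (0.250 to 0.799). No list held a peak on Y, mitochondrial or unplaced sequence, and 0 of 2776 tunicamycin peaks allows a share of up to 0.108% by the same limit. Chromosome 11 held 7.94% of starvation peaks (6.71 to 9.33) and 6.74% of tunicamycin peaks (5.83 to 7.69), and chromosome 5 held 7.24% (6.06 to 8.57) and 8.39% (7.39 to 9.49).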

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

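Of 57 repeats of the main values under another setting, 31 stayed and 26 moved. A count stayed if within 1.5 times its main value, and a share if within the interval of the main share. A score difference stayed if it shifted by no more than 50% of the width of its main relabelling range. A change of direction was defined for score differences only, and 0 of these changed sign. Among 36 repeats of covered lengths and region counts, 24 stayed within 1.5 times and 12 moved, 1 up and 11 down. At a score of at least 68, the control median, 217 control peaks remained, and at 108 or more the lists held 110, 704 and 1329 peaks in control, starvation and tunicamycin, in the same order as before. No list held a peak on Y, mitochondrial or unplaced sequence, so dropping these could change no count. Merging peaks within 500 bp or using 1 lowest −log10 p (added after seeing the data) moved each by under 1.5 times. That −log10 p is the lowest of the control list, which it could not change. The score cuts of 68 and 108 are the median and 75th percentile of the control list, so they set how many of its peaks remain. With such fixed outcomes among them, the counts of repeats that stayed or moved do not measure robustness. With a 50% reciprocal overlap, control peaks were found in starvation at 33.6% and in tunicamycin at 16.8%, and starvation and tunicamycin peaks in control at 8.29% and 2.56%. Peak width limits this rule: in the regions of all 3 lists the median was 207.5 bp in control, 394 bp in starvation and 457 bp in tunicamycin. With a common score threshold the shares were 57.6% of control in starvation, 52.5% of control in tunicamycin, 10.2% of starvation in control and 78.1% of starvation in tunicamycin. With the top 422 peaks of each list they were 38.4% of control in starvation, 38.2% of starvation in control, 36.7% of tunicamycin in control and 65.6% for starvation and tunicamycin either way. For control those 422 are the whole list, so only the stress lists were cut, to their strongest peaks. In those equal lists 6 regions were in control and tunicamycin without starvation and 12 in control and starvation without tunicamycin. For peaks at the genome-wide background only (added after seeing the data), control peaks were found in starvation at 54.9% and in tunicamycin at 47.1%, starvation peaks in control at 8.06% and in tunicamycin at 79.0%, and tunicamycin peaks in control at 3.89% and in starvation at 42.4%. In the narrower 50% of each list the score difference of shared and unshared peaks was 16.5 in control (relabellings −14 to 12), 17 in starvation (−8 to 12) and 8 in tunicamycin (−8 to 8), the last no longer outside its relabellings. Apart from the limit that peak width sets on reciprocal overlap, the causes of these moves were not tested. The alternatives planned for promoter share, gene lists and E-box content were not run. No paired analysis was possible because each group had 1 library and no test was made. The weakest summits rested on 19, 20 and 26 tags in the control, starvation and tunicamycin lists, and weaker binding was not detectable at this depth.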

Other observations

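The thinning tests were set before their results were seen; the tests of the q-value threshold, immunoprecipitation efficiency, strongest and lower-scored control peaks, local background, chance positions, carry-over and list length, and the tag, chromosome and neighbour comparisons, were chosen after the values they rest on had been seen in whole or in part. Recovered tag numbers, divided by depth, allowed a look at the same regions across libraries, with no replicate behind it. At the 169 regions called in all 3 lists, the median was 22.8 tags per unit of IgG depth in control, 51.9 in starvation and 63.4 in tunicamycin. The median ratio per region was 2.13 for starvation over control (interquartile range 1.90 to 2.43, above 1 in 168 of 169) and 2.71 for tunicamycin over control (2.32 to 2.99, above 1 in 166 of 169). Longer fragments raise the number of tags over a summit; after division by the full ratio of fragment lengths the medians were 1.64 and 1.91, above 1 in 165 and 166 regions. At the regions shared by the 2 stresses but not control, tunicamycin over starvation was 1.23 (0.988 to 1.49) over 1110 regions with both tag numbers, and 1.12 after the same division. At the 32 regions in control and starvation without tunicamycin, starvation over control was 0.933 (0.722 to 1.23), above 1 in 14 of 32. After the division it was 0.720, above 1 in 6 of 32. This class differs from the 169 regions by the lack of a tunicamycin call, and starvation peaks of lower score more often lacked one. The choice of class thus favours weak starvation signal and lowers the ratio by itself. The lower ratio is therefore not evidence of another direction at these regions.

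The shorter control list was the first pattern weighed. Depth and fragment length argue little for it: after tags were thinned to the control library's depth and fragment length, 1625 of 1703 starvation peaks (1603 to 1642 over 200 draws) and 2501 of 2767 tunicamycin peaks (2446 to 2534) still passed the lowest −log10 p of the control list, which holds 422. A looser q-value threshold does not account for it either, since 1709 of 1712 starvation peaks passed that same −log10 p. A less efficient immunoprecipitation in the control library stays open: the control list held 37.6% of the top 25% of starvation peaks by score and 4.21% of the lowest 25%, which lower efficiency and lower TFE3 occupancy in unstressed cells both give. With 1 library per condition these cannot be told apart, and stress itself remains an untested explanation.

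The second pattern was the 220 control peaks found in neither stress list. Counting chance alone is argued against for the strongest control peaks: of all 105 in the highest 25% by score, 100 (95 to 104 over 200 draws) would have been expected in the starvation list even at the lower 95% Poisson bound of their control tags and 80 were called, although the spread between libraries of 1 condition is unknown and not part of that expectation. For the 195 control-only peaks outside that 25%, which rest on a median of 27 tags, selection of high draws keeps chance open. A local background above 1.5 times the genome-wide value is argued against as the cause for most. Of the 220, 29.5% (23.6 to 36.0) lay above it, against 32.7% (26.3 to 39.6) of shared control peaks. A smaller excess was not tested: 20.9% of the 220 lay at the genome-wide background itself. The value was 25% for control peaks in regions of control and starvation without tunicamycin, and 28.2% for those in regions of all 3 lists. A TFE3 site lost under stress and a signal particular to this 1 library both remain possible and untested.

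The third pattern was that 32 of the 252 control peaks outside the tunicamycin list were in the starvation list, while all 170 in the tunicamycin list were in the starvation list too. Chance positions gave at most 3 overlaps in 1000 shifts, and list length works the other way, at −1064 peaks for starvation against tunicamycin. The shifts move peaks freely along a chromosome, so overlap at sites that any library favours stays open. The 2 tests of carry-over of control DNA into the starvation library at one fraction went apart, and it stays open: at a fraction of 0.49 of the control tag rate, which gives the observed total, 22 calls (13 to 31 over 200 draws) were expected among the 63 of the 252 peaks with most tags, and 17 were observed. Against it, the median tag ratio of the called regions was 0.933 and 43.8% had a ratio above 1, where a fraction of 0.47, refitted with the control rates drawn around their tags, gave 0.634 (0.553 to 0.735) and 1.45% (0 to 9.68), but those draws hold counting error only and the spread between libraries is unknown. Whether these sites are a state that 2 hours of starvation leaves in part and 16 hours of tunicamycin does not was not tested, and the pattern is a hypothesis: in the lists of equal length it read 12 against 6.

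Of the 220 control-only peaks, chromosome 15 held 26 (11.8%, 7.87 to 16.8), against 99 of 1712 starvation peaks (5.78%, 4.72 to 6.996), and chromosome 11 held 3 (1.36%, 0.282 to 3.93), against 136 of 1712 (7.94%, 6.71 to 9.33). Within the control list itself, the 202 shared peaks had 6.93% (3.84 to 11.4) on chromosome 15 and 9.41% (5.76 to 14.3) on chromosome 11, with intervals that overlap those of control-only peaks on chromosome 15 and lie above them on chromosome 11. Over all chromosomes, relabelled peaks differed by as much as the control-only peaks did from shared control peaks in 833 of 10000 relabellings, from starvation peaks in 28 and from tunicamycin peaks in 75. Both chromosomes were picked after seeing the values, and the intervals and relabellings cover counting error over peaks of 1 library each, so they do not test a difference between conditions. Another peak of the same list lay within 10 kb of 22 of the 220 control-only peaks (10.0%, 6.37 to 14.7) and of 7 of the 202 shared control peaks (3.47%, 1.40 to 7.01). In the starvation list the unshared and shared values were 6.43% (4.28 to 9.22) and 4.57% (3.49 to 5.85), and in the tunicamycin list they went the other way, at 3.03% (2.22 to 4.04) and 4.80% (3.70 to 6.11). The control-only neighbours include a pair on chromosome 15 at 11758741 to 11759226 and 11760448 to 11760887.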
